A study of Mus musculus with 51 samples.

How the data were processed

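The samples are fetal kidneys of C57BL/6 mice at 13 time points, grouped by the time in each sample's label. Per the labels' protocols, RNA was enriched for poly-A transcripts, made into libraries with an Illumina TruSeq kit and sequenced on HiSeq instruments. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5.2b and featureCounts 1.5.0-p3 on the mm10 build. The gene annotation and the normalisation are not given in the sources used here.

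The expression table deposited by the authors is named for counts but holds another unit, treated here as a score: whole numbers that were normalised before they were rounded. This was read from the values. Library totals lie from 34226024 to 35711911 and upper quartiles from 2375 to 2425.5. Among genes with a mean from 1 to 3, the variance within time points was 0.706 times the mean in CT0 to CT24, below counting noise, and 3.41 times the mean in CT28 to CT48. The means of the parts were nearly equal gene by gene, with a standard deviation of the log2 difference of 0.0156. Depth per library is therefore unknown, no counting interval was computed, and precision is given by the spread between libraries. No pair of libraries had identical values. The other deposited table holds the authors' p-values and q-values of a rhythm test, with column names of the MetaCycle package (JTK and Lomb-Scargle tests and their combination), and period and phase scores, per the file headers. It was used only where it is named.

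The planned tests needed raw counts and could not be applied to this unit. In their place each planned model was fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend and robust moderation, for genes with a mean of at least 10 over the 51 libraries (14426 of 16099). Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Benjamini-Hochberg adjusted p under 0.05 was the threshold in each comparison. The models were a 24 h cosine and sine with a line and a step between CT24 and CT28, a line with 24 h terms (the developmental trend, per 24 h), a difference among time points, 3 contrasts at the same clock time, and the interaction of the 24 h terms with the part. All libraries entered each model. The trend with a step as a result of its own, lines in each part, and the difference of slopes were chosen after the values had been seen.

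The comparisons, the gene lists, the naming rule and most other settings were fixed before the data were examined. Named genes are the tested core clock genes, the 10 largest 24 h amplitudes past the threshold, the 10 largest rises and falls of the trend with the same sign in both parts, and the 5 largest rises and falls of each contrast whose 2 groups do not overlap, with a mean of at least 2 in 1e6 of the library total. Predicted gene models, pseudogenes and sex-linked genes were left out of these ranks. As the planned trend called no gene, the rule was applied to the trend with a step. From each of the 28 lists up to 4 members with the largest effect past the threshold are named, or the member with the smallest p. Some genes that these rules select are not reported here. Members named for CT28 to CT48 alone were chosen after their values were seen. Lists of other tissues (liver, adrenal, adipose, skeletal muscle, erythroid) were included, and 6 genes are in more than 1 list.

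Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and by permuting residuals of the list mean 100000 times over libraries and over the 13 time-point means. Gene symbols are those of the table, and 15979 of 16099 were found in the GENCODE M21 annotation of GRCm38, the build also called mm10. In it Nr1d1 (ENSMUSG00000020889.11) is a protein-coding gene at chromosome 11, 98767932 to 98775333, Cirbp (ENSMUSG00000045193.13) at chromosome 10, 80165985 to 80172786, and Umod (ENSMUSG00000030963.6) at chromosome 7, 119462711 to 119479282. Whether reads were assigned by strand is not given in the sources used here, so overlapping genes and close copies such as Hspa1a and Hspa1b, or Cyp4a10 and Cyp4a14, are uncertain as single genes. Transcripts of the mitochondrial genome, 1 clock gene and some sex-linked and globin genes of the lists were not analysed here.

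Each model was tested on simulated data with the real means and the spread of each part, with 100 genes changed by 0.25 and 100 by 0.5 among 14426. For the 24 h rhythm (amplitude) 85% and 96% were recovered, for the developmental trend 82% and 99%, for the trend with a step 51% and 86%, and for CT24 against CT0 43% and 73%. For CT48 against CT24 the shares were 40% and 81%, for CT48 against CT0 41% and 80%, for the rhythm difference 67% and 88%, and for any difference (1 time point changed) 27% and 74%. Unchanged genes made up 22.3% of the calls for any difference, 10.4% for CT48 against CT0, 8.28% for the rhythm difference and 6.2% for CT48 against CT24. These shares are above the nominal 5%, while that for CT24 against CT0 was 0%. The simulated spread was larger in CT28 to CT48, but each fit used a single spread for all libraries. Such a mismatch can give too many calls for CT28 to CT48 and too few for CT0 to CT24, and was not tested as the cause. The simulated libraries were independent of each other. In the real data the estimated correlation within time points was 0.373 for the rhythm and the trend with a step, and 0.393 for the developmental trend. The shares recovered and falsely called therefore do not carry over to the real data.

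Alternatives were other filters, pseudocounts and scalings, replicate blocks, weights for the parts, single replicates, time points or libraries left out, time points as the unit, an estimated correlation within time points, and other periods and trend terms. Figures were drawn with matplotlib 3.10.9.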

Results

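Poly-A RNA was sequenced from kidneys of C57BL/6 mouse fetuses collected every 4 h over 48 h, from embryonic day 18 to embryonic day 20. Time is given below as hours of the series (CT0 to CT48), with CT0 on embryonic day 18, CT24 on embryonic day 19 and CT48 on embryonic day 20. These ages follow the sample labels, and the design text of the series names a later end. The series holds 51 libraries at 13 time points, with 3 libraries at CT20 and 4 at each of the other 12. The labels call them biological replicates but do not name dams or litters. The p-values therefore measure the spread between these samples, and fetuses of 1 time point could share a litter. Of the 51 libraries 2, CT12 replicate 4 and CT36 replicate 3, carry another ID prefix, for which no reason is given in the labels. Library numbering separates a first part, CT0 to CT24 (27 libraries), from a second part, CT28 to CT48 (24 libraries). The deposited values are normalised and rounded, so their totals of 34226024 to 35711911 per library do not give sequencing depth, which is unknown. Each gene had nearly the same mean in both parts. The log2 difference between the part means had a standard deviation of 0.0156 over 11448 genes, against 0.0899 between CT16 to CT24 and CT0 to CT8 and 0.279 between CT40 to CT48 and CT28 to CT36. Levels set across CT24 and CT28 are therefore on a scale in which the parts were made alike. Comparisons inside a part do not cross that boundary. Whether values inside a part were rescaled as well is unknown, so sizes of change there may still depend on the normalisation.

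The first question was which transcripts followed a 24 h cycle, as the series title names the circadian clock. Nr1d1, a repressor in the clock's feedback loop, had a fitted log2 amplitude of 0.18 ± 0.03 (SE, 51 libraries) with its peak at 23.7 h (adjusted p = 0.000295). Its mean was 365 ± 12.9 (SD, n = 4) at CT12 and 457 ± 29.5 (SD, n = 3) at CT20. Cry2, a cryptochrome that represses the clock activators, had an amplitude of 0.18 ± 0.04 with a peak at 22.1 h (adjusted p = 0.00489). Cry1 peaked at 15.8 h with an amplitude of 0.13 ± 0.04 (adjusted p = 0.0412), and Dbp, a clock-controlled transcription factor, peaked at 1.3 h with 0.11 ± 0.03 (adjusted p = 0.0468). Those were the 4 of 19 tested core clock genes past the threshold, and 8 passed when adjusted over the list alone. Arntl, the clock activator also known as Bmal1, had an amplitude of 0.16 ± 0.06 and did not pass (unadjusted p = 0.0255), nor did Per1 (0.26 ± 0.11, adjusted p = 0.186) or Per2 (0.09 ± 0.09, adjusted p = 0.683). An excess of clock genes among the genes called did not pass (Fisher's exact test, one-sided, p = 0.198). Of the 11 tested clock output genes 0 passed in limma, and Tspan4 came nearest with an amplitude of 0.06 (adjusted p = 0.0852). Nr1d1 passed without any single time point or replicate number. Cry2 did not without replicate 3 (adjusted p = 0.0505) or CT0 (0.119), and Cry1 (0.0664, 0.206, 0.0939 and 0.245) and Dbp (0.104, 0.0809, 0.169 and 0.275) did not without replicates 1, 2, 3 and 4. Without the 2 libraries of another ID prefix neither Cry1 (0.056) nor Dbp (0.055) passed. With time-point means as the unit Nr1d1 had adjusted p = 0.923.

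Larger cycles were fitted outside the clock. Cirbp, a cold-inducible RNA-binding protein, had an amplitude of 0.64 ± 0.12 and a peak at 20.1 h (adjusted p = 0.00166), with means of 1811 ± 297 (SD, n = 4) at CT12, 4257 ± 204 (SD, n = 3) at CT20, 1208 (libraries 1091 to 1333, n = 4) at CT32 and 5161 (libraries 4983 to 5266, n = 4) at CT40. Ifi27l2a, an interferon-induced gene, had 0.65 ± 0.15 with a peak at 9.9 h. Acta1, skeletal muscle actin, had the largest amplitude under the naming rule (0.99 ± 0.27, adjusted p = 0.026), with a mean of 292 ± 444 (SD, n = 4) at CT40. The mean standardised score of the skeletal muscle list also differed widely between the libraries of CT40, from -0.963 to 3.23 (n = 4). Others among the 10 largest were Kcne3 (0.55), Lrrc29 (0.55), Rmi2 (0.53), Stab2 (0.51), Il27ra (0.47) and Ctxn3 (0.45). Cirbp passed without any single time point or replicate number. Ifi27l2a did not without replicate 2 (adjusted p = 0.0996) or 3 (0.0717), and without replicate 4 neither Acta1 (0.117), Kcne3 (0.244), Lrrc29 (0.153), Rmi2 (0.103), Stab2 (0.11), Il27ra (0.212) nor Ctxn3 (0.0809) did. In total 1773 of 14426 genes passed, with a median peak-to-trough ratio of 1.19, and 131 of them reached 1.5. Peaks lay most often between 20 and 24 h (500 genes, 28.2%), between 4 and 8 h (387 genes) and between 8 and 12 h (372 genes). With the 13 time-point means as the unit 0 genes passed in limma (533 at an unadjusted p under 0.05), and with an estimated correlation within time points 2 did. The count was 724, 320, 224 and 301 without replicate 1, 2, 3 and 4, and 599, 3714, 933, 665, 738 and 3479 without CT0, CT8, CT12, CT32, CT44 and CT48.

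**Figure D1:**
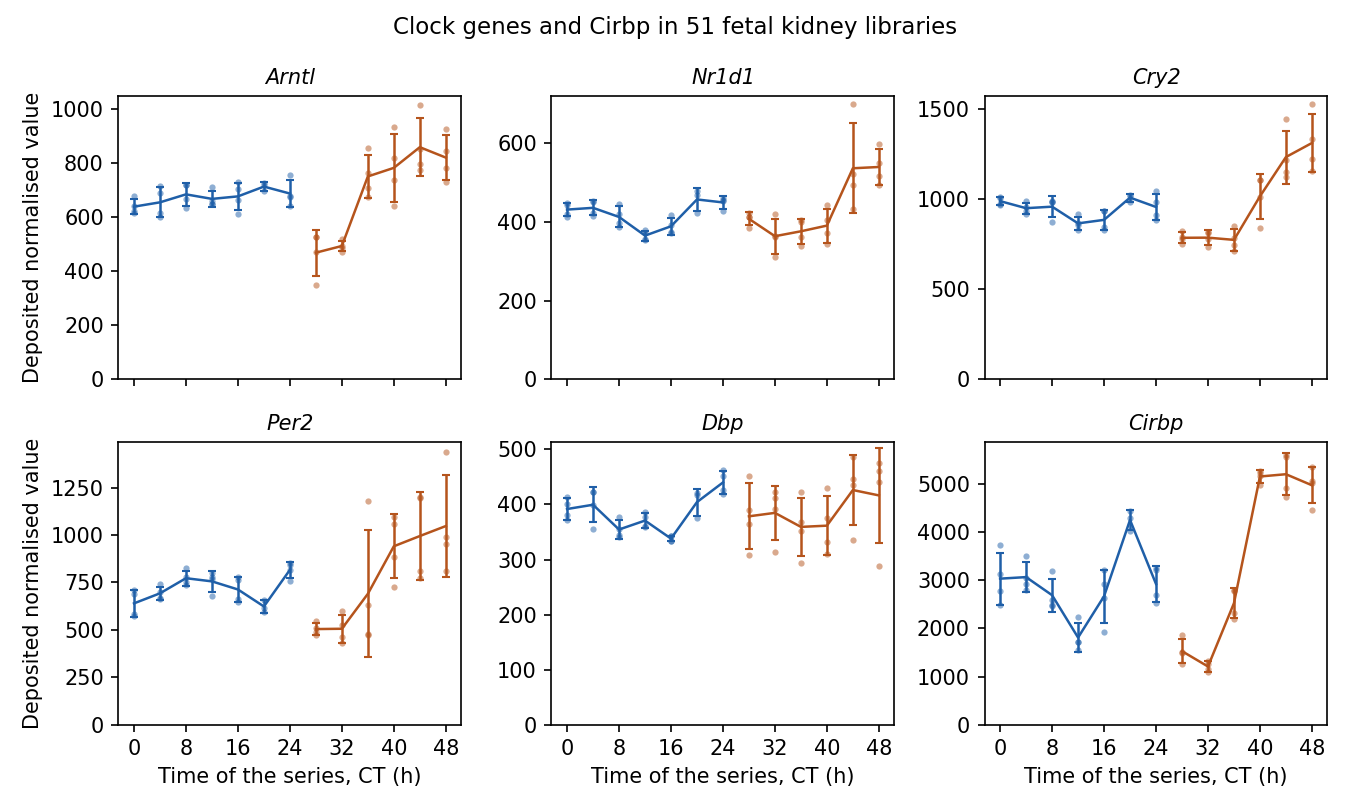
Deposited normalised values (y axis) against hours of the series (x axis) for 5 clock genes and Cirbp; points are libraries, lines join time-point means, and bars are 1 SD with n = 4 (3 at CT20). Blue marks CT0 to CT24 and orange CT28 to CT48, and Cirbp has means of 1208 at CT32 and 5161 at CT40.

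Of the other gene groups, heat shock and chaperone genes had 8 of 15 members past the rhythm threshold (10 adjusted over the list alone). Beside Cirbp these included the chaperones and co-chaperones Hsph1 (0.37, adjusted p = 0.00112), Chordc1 (0.36, adjusted p = 0.000812) and Hspa8 (0.21, adjusted p = 0.000703). Collecting duct genes had 9 of 17 members past it (11 adjusted over the list alone), led by the water channel Aqp2 (0.29, adjusted p = 6.76e-06) and the proton pump subunit Atp6v1b1 (0.25). Proximal tubule genes had 7 of 24 (11 adjusted over the list alone), among them Gatm (0.37) and the phosphate transporter Slc34a1 (0.20), and podocyte genes had 6 of 14 (6 adjusted over the list alone), among them Nphs1, which encodes nephrin (0.11). The list mean had a 24 h component for heat shock genes (permutation test over 51 libraries, adjusted p = 0.00054) and for proximal tubule genes (permutation test, adjusted p = 0.0445). Over the 13 time-point means neither passed (permutation test, adjusted p = 0.409 and 0.766), and no other list did.

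The fitted 24 h terms differed between the parts. Arntl had a fitted amplitude of 0.06 in CT0 to CT24 and 0.36 in CT28 to CT48 (adjusted p for the difference = 9.99e-06), and Hlf, a clock-controlled transcription factor, had 0.12 and 0.40 (adjusted p = 3.84e-07). Cirbp peaked at 23.7 h in the first part and 19.2 h in the second (adjusted p = 4.07e-08). The difference passed for 14 of 19 core clock genes (16 adjusted over the list alone), 20 of 24 cell cycle genes and 13 of 15 heat shock genes. Dbp (adjusted p = 0.705), Rorb (0.691), Bhlhe40 (0.225), Bhlhe41 (0.064) and Nr1d2 (0.0531) were the clock genes that did not pass. Across all genes 6778 of 14426 passed, and 4465 without CT28 and CT32, an alternative chosen after seeing the data. Each part spans 24 h or less, so a cycle cannot be separated there from a curved change with age. The model also holds a common slope for both parts, so a straight change of another size in each part can enter these terms. Lines fitted to each part alone had slopes that differed for 7641 genes, and those of Arntl were 0.11 and 1.12 per 24 h. These amplitudes and counts therefore do not show that a rhythm changed.

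The comparison of embryonic day 19 with embryonic day 18 at the same clock time, CT24 against CT0, lies inside the first part. Genes of the differentiated nephron were higher at CT24. Umod, the uromodulin of the thick ascending limb, went from 4339 ± 390 to 8510 ± 454 (SD, n = 4 each), a log2 difference of 0.97 ± 0.10 (SE, adjusted p = 2.99e-08). Aqp2 went from 7933 ± 795 to 13410 ± 567, a difference of 0.76 ± 0.13 (adjusted p = 0.000189). Kap, an androgen-regulated protein of the proximal tubule, went from 4943 ± 514 to 11450 ± 2480 (1.19 ± 0.21, adjusted p = 0.000161). Six2, which maintains nephron progenitors, had means of 2618 and 2174 and fell by 0.27 ± 0.07 (adjusted p = 0.0143), and the mitotic cyclin Ccnb1 fell by 0.36 ± 0.06 (SE). Proximal tubule genes rose in 17 of 24 tested members and fell in 0 (21 rose adjusted over the list alone), with Pck1 (0.90), G6pc (0.78) and Miox (0.78) behind Kap. Loop of Henle and distal tubule genes rose in 10 of 15 (12 adjusted over the list alone), including Tmem207 (0.92), the magnesium channel Trpm6 (0.70) and the thiazide-sensitive transporter Slc12a3 (0.66). Collecting duct genes rose in 4 of 17 (4 adjusted over the list alone), with Aqp3 (0.53) and the sodium channel subunits Scnn1g (0.32) and Scnn1b (0.20) beside Aqp2. Cell cycle genes fell in 21 of 24 (24 adjusted over the list alone), with Bub1 at -0.42, Ccne1 at -0.38 and Mcm5 at -0.35. These 4 lists held in camera with an estimated correlation (adjusted p = 0.0171, 0.0022, 0.0171 and 0.0258 with an estimated correlation). Without CT24 replicate 2 the counts were 14, 9, 4 and 12.

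Other groups moved in fewer members between CT0 and CT24. Nephron progenitor genes fell in 4 of 12 and rose in 2 (6 and 2 adjusted over the list alone), with Eya1 at -0.45, Cited1 at -0.27 and Meox1 at -0.26 (camera adjusted p = 0.00745, adjusted p = 0.225 with an estimated correlation). Podocyte genes rose in 5 of 14 (7 rose and 1 fell adjusted over the list alone), led by the glomerular basement membrane collagens Col4a3 (0.66) and Col4a4 (0.62), with camera adjusted p = 0.139 with an estimated correlation. Fatty acid oxidation genes rose in 10 of 20 (11 adjusted over the list alone), led by the omega-hydroxylases Cyp4a14 (1.58) and Cyp4a10 (1.14), and Ppara, their nuclear receptor, rose by 0.47 (adjusted p = 0.139 with an estimated correlation). Cholesterol synthesis genes fell in 6 of 17 (8 adjusted over the list alone), with Insig1 at -0.46 and Fdps at -0.26 (adjusted p = 0.235 with an estimated correlation). Hypoxia response genes rose in 5 of 16 (7 adjusted over the list alone), with Ndrg1 at 0.71, Ankrd37 at 0.66 and Epo, erythropoietin, at 2.21 ± 0.71 (adjusted p = 0.235 with an estimated correlation). Epo was low, at 2.25 ± 1.5 and 16 ± 11.9 (SD, n = 4 each). Macrophage genes rose in 4 of 14 (6 adjusted over the list alone), with Csf1r at 0.52 and C1qa at 0.36 (adjusted p = 0.139 with an estimated correlation). Stroma genes fell in 2 of 15 (Foxd1 -0.36, Meis1 -0.27; 3 adjusted over the list alone), endothelial genes rose in 1 of 15 (Plvap 0.22; 4 adjusted over the list alone, adjusted p = 0.235 with an estimated correlation), and core clock genes rose in 2 of 19 (Bhlhe40 0.54, Hlf 0.33; 2 adjusted over the list alone, adjusted p = 0.235 with an estimated correlation). The clock output list rose in 2 of 11 (Hsd11b1 0.70, Por 0.18), the glucocorticoid response list in 1 of 19 (Cdkn1a 0.44; adjusted p = 0.609 with an estimated correlation), oxidative phosphorylation in 1 of 20 (Ndufv1 0.17; adjusted p = 0.523 with an estimated correlation), immediate early genes in 1 of 15 (Ier3 0.63; 2 adjusted over the list alone), and heat shock genes rose in 1 (Cryab 0.37) and fell in 2 of 15 (Hsp90aa1 -0.22, Hsp90ab1 -0.13).

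Markers of neighbouring or contaminating tissue were read in the same contrast. The liver list rose in 1 of 10 members, Ttr, by 1.21 ± 0.25 (adjusted p = 0.000984; list adjusted p = 0.313 with an estimated correlation). In limma 0 of 8 adrenal, 0 of 4 adipose, 0 of 8 skeletal muscle, 0 of 7 erythroid and 0 of 4 sex-linked genes passed, with Nr5a1 (0.58, adjusted p = 0.409), Pparg (0.13, adjusted p = 0.665), Actn3 (-0.35, adjusted p = 0.252), Alas2 (-0.22, adjusted p = 0.672) and Uty (-0.36, adjusted p = 0.504) nearest. No member passed among 12 ureteric bud tip genes (Spry1 0.15, adjusted p = 0.133), 14 early nephron genes (Sfrp2 -0.16, adjusted p = 0.0634) and 14 vascular growth and Notch genes (Vegfa 0.22, adjusted p = 0.0641). Transcripts of the mitochondrial genome were not analysed here.

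Large changes from CT0 to CT24 among genes with a mean of at least 2 in 1e6 of the library total were also found outside these lists. Ifi27l2a rose from 187 ± 76.9 to 1076 ± 119 (SD, n = 4 each), a log2 difference of 2.60 ± 0.34 (SE, adjusted p = 2.02e-06). The interferon-induced genes Gbp6 and Oas2 rose by 1.59 ± 0.36 and 1.35 ± 0.32. Lgals3bp rose by 1.32 ± 0.18. Gsdmc2, of the gasdermin family, fell by 1.10 ± 0.22 (adjusted p = 0.00083), and lower too were Fndc3c1 (-0.69), the glycosyltransferase B3gnt5 (-0.65) and Emilin3 (-0.62). For each of these genes the 4 libraries of one time point all lay above the 4 of the other, which the naming rule required. Overall counts were 872 genes higher and 571 lower at CT24, 1443 of 14426 tested. The share higher was 60.4%, and the excess was smaller in some other fits, at 51.4% with quantile scaling, 53% with part weights, 53.4% with only the 2 groups and 54% with only CT0 to CT24. The count fell to 864, 880 and 773 without CT0 replicate 2, CT0 replicate 3 and CT24 replicate 2, while the share higher grew to 63%, 63.7% and 64.3%. The count was 3832 when only CT0 to CT24 entered the fit, where the spread between libraries was smaller (median SD of log2 values 0.0748, against 0.136 in CT28 to CT48).

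**Figure D2:**
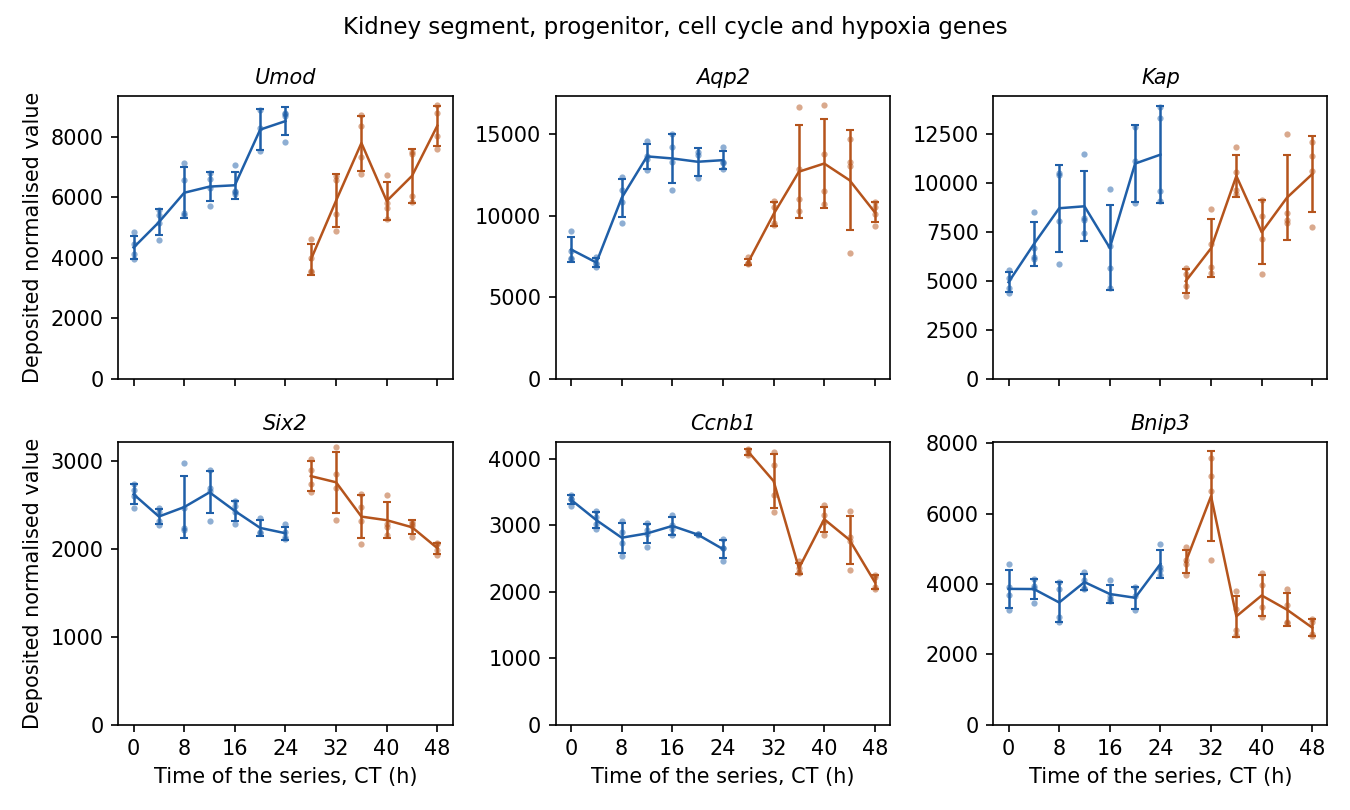
Deposited normalised values (y axis) against hours of the series (x axis) for a loop of Henle gene (Umod), a collecting duct gene (Aqp2), a proximal tubule gene (Kap), a nephron progenitor gene (Six2), a cell cycle gene (Ccnb1) and a hypoxia response gene (Bnip3); points are libraries, lines join time-point means and bars are 1 SD with n = 4 (3 at CT20). Umod has means of 4339 at CT0, 8510 at CT24, 3935 at CT28 and 8360 at CT48, with the means of the blue and orange parts of the series made alike in the deposited values.

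The developmental trend over the whole series was tested as a straight line with 24 h terms. In limma 0 of 14426 genes passed (224 at an unadjusted p under 0.05). The same fit without CT28 and CT32, which stood apart on the first principal component and were left out after that was seen, gave 6044 genes. The 0 thus depends on those time points and on the equal part means, which leave little room for a line across the series. The median slope of proximal tubule genes was 0.0876 per 24 h in the planned fit and 0.535 with a step in the fit. Without CT28 and CT32 the part means are no longer equal, so the 6044 genes cannot be read as a trend that those time points hid. The fit was repeated with a step between CT24 and CT28, after the equal means had been seen, so that the slope is the change per 24 h inside the parts. Genes of tubular metabolism and transport then rose: Cyp4a10 by 1.99 ± 0.45 per 24 h (SE, log2, adjusted p = 0.00137), the gluconeogenic enzymes G6pc by 1.54 ± 0.47 and Pck1 by 1.44 ± 0.29, the urea transporter Slc14a2 by 1.44 ± 0.31, the vitamin D hydroxylase Cyp24a1 by 1.37 ± 0.35, Gsta1 by 1.44 ± 0.41 and Agt, angiotensinogen, by 1.53 ± 0.25 (adjusted p = 2.14e-05). Ifi27l2a had a slope of 2.08, from the first part: lines in each part alone gave 2.31 and 0.04 (adjusted p = 0.955 for the second), and the slopes differed (adjusted p = 0.0251). The chemokine Cxcl13 fell by 1.44 ± 0.41, cardiac actin Actc1 by 1.21 ± 0.47 (adjusted p = 0.0494), Cntn6 by 1.10, the matrix proteoglycan Lum by 1.01, the glutamate transporter Slc17a8 by 0.97, Gsdmc2 by 0.86, Ryr1 by 0.80, the retinoic acid binding protein Crabp2 by 0.79 ± 0.14 (adjusted p = 9.53e-05), Depdc1a by 0.78 and the cell cycle phosphatase Cdkn3 by 0.76. In all 1860 genes rose and 1943 fell. With time-point means as the unit 19 genes passed, with an estimated correlation within time points 364, without CT28, without CT48 and without both CT28 and CT32 1500, 913 and 2157. The count was 1980, 1879 and 1839 without replicate 1, 2 and 3. Agt, Pck1, Slc14a2 and Crabp2 passed without any single time point or replicate number, while without CT48 Cyp4a10 (adjusted p = 0.11), G6pc (0.303), Gsta1 (0.331), Cyp24a1 (0.0901), Cxcl13 (0.159), Cntn6 (0.071), Lum (0.0661), Slc17a8 (0.0761), Ryr1 (0.093), Depdc1a (0.0583), Cdkn3 (0.303) and Actc1 (0.113) did not. Gsdmc2 did not without CT24 (0.213) or replicate 3 (0.0866), Cyp24a1 without CT0 (0.143), and G6pc (0.119), Gsta1 (0.0793), Cxcl13 (0.0719) and Ryr1 (0.053) without CT28. G6pc also did not without replicate 1 (0.0895) or 2 (0.0833), nor Cxcl13 without replicate 2 (0.0593), and Actc1 did not in most such fits.

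By list, the slope with the step was upward for proximal tubule genes in 20 of 24 members (22 adjusted over the list alone; Kap 1.30), for loop of Henle and distal tubule genes in 9 of 15 (10; Umod 1.13 ± 0.11), and for collecting duct genes in 7 of 17 with 1 downward (8 and 1; Aqp2 0.74). These 3 lists held with an estimated correlation (camera, adjusted p = 0.0192 with an estimated correlation for each). On a line through CT28 to CT48 alone they did not (camera, adjusted p = 0.702, 0.655 and 0.655 with an estimated correlation). There 11 rose and 2 fell, 9 rose and 3 fell, and 9 rose and 5 fell. On a line through CT0 to CT24 alone the camera adjusted p was 0.0721, 0.0175 and 0.0947 with an estimated correlation. A rise of these lists in both parts is thus not shown. Fatty acid oxidation genes rose in 17 of 20 (20 adjusted over the list alone; Cyp4a14 2.54, Ehhadh 1.10; adjusted p = 0.173 with an estimated correlation), and cell cycle genes fell in 20 of 24 (20; Birc5 -0.67, Ccnb1 -0.62; adjusted p = 0.173 with an estimated correlation). Macrophage genes rose in 6 of 14 (7; Csf1r 0.77; adjusted p = 0.146 with an estimated correlation), and podocyte genes in 5 of 14 (5; Col4a3 0.93; adjusted p = 0.14 with an estimated correlation). Core clock genes rose in 5 of 19 (9; Per2 0.55, Rora 0.52, Hlf 0.52; adjusted p = 0.353 with an estimated correlation). Nephron progenitor genes fell in 6 of 12 and rose in 2 (Cited1 -0.39, Six2 -0.33, Itga8 0.36; adjusted p = 0.343 with an estimated correlation). The liver marker Ttr rose by 1.28 in the same fit, as 3 of 10 liver genes did (5 adjusted over the list alone; adjusted p = 0.353 with an estimated correlation), while 1 of 8 skeletal muscle genes fell (Actn3 -0.55).

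Lines fitted to each part alone, also added after the equal means were seen, gave larger slopes in the second part. From CT28 to CT48 the glucocorticoid response genes Pdk4, Klf9 and Fkbp5 rose by 3.22 ± 0.44, 2.20 ± 0.25 and 1.64 ± 0.31 per 24 h (SE, log2, 24 libraries), against slopes of 0.30, 0.27 and -0.07 from CT0 to CT24. The slopes differed between the parts for each (adjusted p = 1.19e-06, 2.5e-08 and 9.82e-06). Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, rose by 2.06 ± 0.24. Of the clock genes Arntl rose by 1.12 ± 0.16 and Per2 by 1.46 ± 0.23. Hypoxia response genes fell, P4ha1 by 1.97 ± 0.27, the lactate dehydrogenase gene Ldha by 1.43 ± 0.23 and Bnip3 by 1.10 ± 0.24. By list, 14 of 19 glucocorticoid response genes rose and 1 fell, 18 of 20 fatty acid oxidation genes and 16 of 19 core clock genes rose, 24 of 24 cell cycle genes and 14 of 20 oxidative phosphorylation genes fell while 3 rose, and 10 of 16 hypoxia response genes fell while 2 rose (adjusted over the list alone 15 and 1, 18, 17, 24, 14 and 4, 10 and 2). Libraries of 1 time point differed widely in the glucocorticoid response score, from -0.909 to 1.62 at CT36, -0.387 to 1.77 at CT44 and -0.571 to 2.03 at CT48 (n = 4 each). None of these lists held in camera with an estimated correlation (lowest adjusted p = 0.589 with an estimated correlation). The members were picked for description after their values were seen. Over all genes 4134 rose and 4427 fell, against 1866 and 1444 from CT0 to CT24, and the slopes differed for 7641 genes. The libraries of CT28 and CT32 stood apart from those of CT36 to CT48, and on CT36 to CT48 alone 559 genes rose and 515 fell, with 2 glucocorticoid response, 3 core clock and 0 fatty acid oxidation genes upward and 0 cell cycle, 0 oxidative phosphorylation and 1 hypoxia response genes downward in limma.

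Genes that changed in both parts mostly kept their direction. Of 2298 genes past the threshold in both, 1041 rose in both (535 for independent lists) and 993 fell in both (443 for independent lists), while 213 rose then fell (573) and 51 fell then rose (414). The slopes of the parts had a Pearson r of 0.344 and a Spearman rho of 0.442 across genes, which are not independent replicates. The libraries of the parts are separate.

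Embryonic day 20 was set against embryonic day 19 and 18 at the same clock time, across the parts. At CT48 against CT24, smooth muscle actin Actg2 was higher by 1.77 ± 0.44 (SE, log2, n = 4 each, adjusted p = 0.00312), the haem oxygenase Hmox1 by 1.27 ± 0.21, Cyp4a10 by 1.09 ± 0.30 and the lipase inhibitor Angptl4 by 1.08 ± 0.21. Isg15 (-2.20 ± 0.37), Gbp6 (-1.93), Ifi27l2a (-1.78) and Oas2 (-1.46), which are interferon-induced, and the neuropeptide Vip (-1.42) were lower. Hypoxia response genes fell in 11 of 16 (11 adjusted over the list alone; Epo -1.96, Ankrd37 -1.15, P4ha1 -0.78, Bnip3 -0.73), oxidative phosphorylation genes in 9 of 20 (10; Cox6c -0.36), and fatty acid oxidation genes rose in 13 of 20 (14). Proximal tubule genes rose in 2 of 24 and fell in 2. At CT48 against CT0, Cyp4a10 was higher by 2.23 ± 0.30 (adjusted p = 3.68e-07), G6pc by 1.84 ± 0.23, Cyp24a1 by 1.72 ± 0.29 and Gsta1 by 1.65 ± 0.20. Cxcl13 (-1.43), Cntn6 (-1.34), Vip (-1.29), Dynlt1f (-1.28) and Proca1 (-1.14) were lower. Cxcl13 did not pass without CT48 replicate 2 (adjusted p = 0.0749). Fatty acid oxidation genes rose in 19 of 20 (19 adjusted over the list alone), proximal tubule genes in 18 of 24 (20) and immediate early genes in 7 of 15 (10; Ier3 1.05). CT48 replicate 2 stood apart in the last list, with Fos at 554 against 130 to 156 and Egr1 at 3081 against 1175 to 1815 in the other 3 libraries, and list scores at CT48 ran from 0.0533 to 2.73. Cell cycle genes fell in 17 of 24 (18; Birc5 -0.74). The liver genes Fga (1.27) and Ttr (1.23) were among 4 of 10 liver genes that rose. The counts were 1704 higher and 2138 lower for CT48 against CT24, and 2884 and 2982 for CT48 against CT0. These 2 contrasts share the CT48 libraries, and both cross the boundary at which the part means were made alike. A single spread for all libraries entered the fits, while libraries of CT28 to CT48 varied more (median SD 0.136 against 0.0748). In simulated data unchanged genes made up 6.2% and 10.4% of the calls. The p-values at CT48 may therefore be too small, and these counts are not comparable with the 1443 for CT24 against CT0.

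Any difference among the 13 time points was found for 10708 of 14426 genes. This count may be too high, as unchanged genes made up 22.3% of such calls in simulated data. The first principal component held 25.8% of the variance and had means of 33.5 at CT28 and 32.3 at CT32 (n = 4 each). It was 5.26 at CT0 and -4.41 at CT24, and -7.13, -12.9, -23.3 and -27.2 at CT36, CT40, CT44 and CT48.

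**Figure D3:**
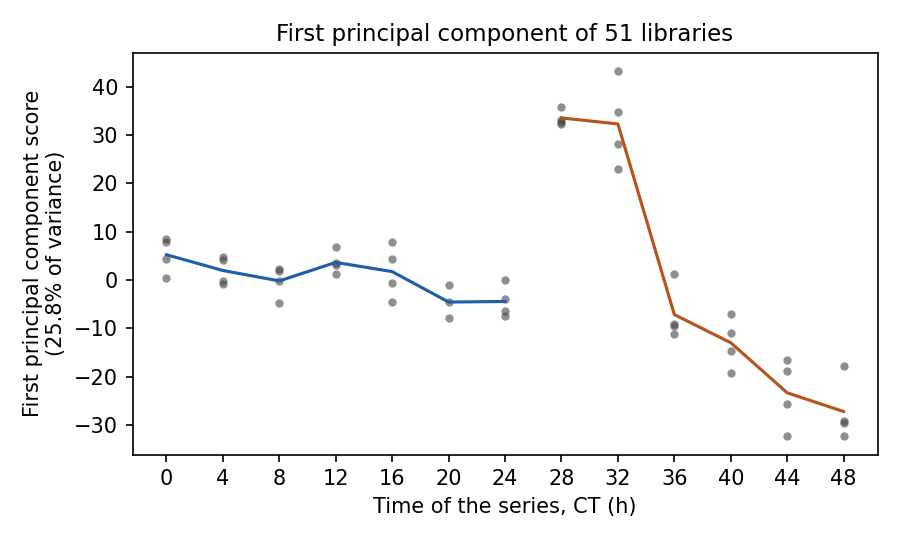
First principal component score (y axis, no unit) of the 51 libraries against hours of the series (x axis); points are libraries and lines join time-point means within each part. The 8 libraries of CT28 and CT32 lie from 23 to 43.2, above the highest of the others at 8.44.

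The authors' deposited table gives a rhythm test per gene over the whole series. There, 6647 of 16099 genes had a combined q under 0.05 per the authors' deposited values. Of these 3585 (53.9%) had a period of 27 h or more, and 932 and 886 had periods of 22 to under 24 h and 24 to under 26 h. Nr1d1 had q = 1.06e-07 and a period of 23.8 h in the authors' deposited table, and Cry2 had q = 2.33e-06 and 24.4 h. Arntl, Clock, Per2, Cry1 and Hlf each had a period of 28 h in the authors' deposited table, with q of 7.75e-06, 0.00067, 0.00242, 2.67e-07 and 4.61e-06, and 15 of 19 core clock genes had q under 0.05. Of the 1773 genes with a 24 h component here, 1507 (85%) had q under 0.05 in the authors' deposited table, against 40.3% of the other genes. The overlap was counted at any period in the authors' deposited table, so it does not show that both tests found a 24 h period. Both tests draw on the same series, so the overlap is not independent evidence.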

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

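The tests of why the parts differ in size of change were chosen after the results were seen. So were the tests of a separate drift in each part and of a cosine with a step, and the shuffling for the planned trend. The tests of time-point order, of a shared rhythm and of a drift with a common slope were set before their results were seen. How far the tests of a shared rhythm and of a drift with a common slope count was judged after.

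Among groups of 4 libraries, 213 were examined for 1 library far from the others, and 13 had a gap above 0.829 of the range. Chance gives such a gap in about 1 in 20 groups. CT0 replicate 4 was the library apart in 4 of them and CT36 replicate 4 in 2. Dbp at CT48 had 289 in replicate 2 and 440 to 476 in the others (gap 0.842). At CT0, replicate 4 had 514 for Hlf against 441 to 448 (gap 0.897), 55 for Bhlhe41 against 64 to 65 (gap 0.907) and 66 for Gsta1 against 89 to 92 (gap 0.9). At CT24, B3gnt5 had 432 in replicate 3 against 381 to 389 (gap 0.835), and Hmox1 had 1707 in replicate 1 against 2278 to 2394 (gap 0.853).

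Mean standardised scores of gene lists gave the other gaps. In CT36 replicate 4 the immediate early genes had 3.05 against -0.625 to -0.0151 (gap 0.834) and skeletal muscle genes 1.75 against -0.376 to -0.0472 (gap 0.846). Fos was 2161 in that library and 66 to 151 in the other 3. CT40 replicate 2 had 0.772 for immediate early genes against -0.645 to -0.532 (gap 0.921). Erythroid genes in CT16 replicate 2 had -0.486 against -0.15 to -0.124 (gap 0.929). Adrenal genes had 0.297 in CT0 replicate 4 against -0.244 to -0.214 (gap 0.945) and 0.318 in CT24 replicate 4 against -0.00933 to 0.0335 (gap 0.869). Adipose genes in CT4 replicate 1 had -0.000835 against 0.147 to 0.156 (gap 0.943).

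Changes were larger in CT28 to CT48 than in CT0 to CT24: the 24 h terms differed for 6778 genes and the slopes for 7641. The spread of time-point means, with the spread within time points taken off, was 2.82 times larger in the second part (2.56 to 3.06 with 1 time point left out). More noise between independent libraries therefore does not account for it. Noise shared by the libraries of 1 time point, as from a litter, is not taken off and stays open. Stretched log2 deviations in 1 part stay open, as the quotient of the ratios between and within time points was 1.55 (1.37 to 1.72), and so does the effect of CT28 and CT32, without which the ratio was 1.6 (1.05 to 1.76). Both values passed the limit of 1.5 set for them, but leaving out 1 time point brought each below it, and that requirement was added after they were seen. Age cannot be told apart from the library series, because each age range has 1 series.

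The authors' deposited table had q under 0.05 for 6647 genes, of which over 50% had periods at the long end of the range. The change from CT24 to CT28 had a median of 3.14 times that of a fitted 28 h cosine (quartiles 2.28 to 4, 3575 genes), which alone decides nothing, as equal part means could put a step there. With a step of any size in the fit the ratio was 3.18 (quartiles 2.35 to 3.95), which argues against a smooth 28 h rhythm of constant amplitude as the whole account, while one of changing amplitude stays open. A drift with a common slope and a step explained more variance than the cosine in 36.9% of genes (median share 0.299 against 0.327), under the 50% set before, but stays open because these genes were picked by a rhythm fit, which favours the cosine. A drift of another size in each part explained more than a step and a cosine in 85.6% (median share of variance 0.533 against 0.329), and on values whose part means were made alike it is a candidate explanation of the long periods, while no biological explanation was tested.

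The 24 h rhythm was lost with time points as the unit. When whole time points were reordered within the parts, 40 of 100 orders, the real one included, gave at least the real 1773 calls (highest 8044), so differences between time points without a 24 h order may give as many. Peak times cannot decide whether the parts share a rhythm, because inside a part a cycle cannot be separated from a curved change with age. Of 3015 genes called in CT0 to CT24 alone, 36.2% peaked within 4 h of the same clock time in CT28 to CT48. The share was 31% with the peaks shuffled among genes. Only 294 genes were called in both parts, and 32.7% of these peaked within 4 h. A rhythm shared by the parts is thus neither shown nor excluded.

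Shuffling libraries over time points within the parts gave as many calls as the real order in 1 of 100 splits, the real one, for any difference (10708, highest other 2727). A chance assignment of single libraries to time points is unlikely there, while a chance difference between litters is not tested. The real order was also the only 1 for the 24 h rhythm (1773, highest other 0), the trend with a step (3803, highest other 0) and the rhythm difference (6778, highest other 1938). For these 3 the shuffling decides nothing about order in time, because it removes every difference between time points, and chance is not excluded by it. For the planned trend its outcome was fixed by the real count (0, highest other 0, 100 of 100), so it decides nothing. These splits move single libraries and do not test whether time points share a litter. Among the 35 splits of 8 libraries, only the real one gave as many calls in each contrast. The counts were 1443 for CT24 against CT0 (highest other 2), 3842 for CT48 against CT24 (highest other 1028) and 5866 for CT48 against CT0 (highest other 2074). A chance assignment of single libraries to the time points is thus unlikely, at 1 in 35, the smallest share this test can give. A chance difference between litters is not tested by it. The counts of 1028 and 2074 in other splits point to further structure among those libraries.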

How the results depend on the processing

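Pseudocounts 0.5 and 8, quantile scaling, part weights, fits without CT28 and CT32 or CT36 replicate 4, fits of CT0 to CT24 alone for CT24 against CT0, straight lines in each part, a separate line per part in the rhythm fit, and every setting of the trend with a step were chosen after seeing the data; the rest was planned. RLE size factors, DESeq2 and limma-voom were planned and not run, since they need counts. Where a count moved, the cause was not tested, except that settings with fewer libraries or time points have less power by construction.

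The 24 h rhythm (1773) was 0 with time points as the unit, 2 with an estimated correlation within time points, 6400 with a linear trend only, 7595 with no trend or step, 6049 with a quadratic trend, 65 at a period of 12 h, 3015 in CT0 to CT24 only and 1060 in CT28 to CT48 only. Without CT0, CT8, CT12, CT32, CT44 and CT48 it was 599, 3714, 933, 665, 738 and 3479, and with replicates left out 224 to 1640. Its other 21 settings gave 1206 to 2516. They include a period between 12 h and 24 h and one longer than 24 h, so the number of calls is not particular to 24 h. The developmental trend (0) was 6044 without CT28 and CT32, 3857 in CT0 to CT24 only, 4546 in CT28 to CT48 only, 3310 and 8561 as straight lines there, and 3803 with a step; it was 0 in all others, with replicates left out 0 to 0. The trend with a step (3803) was 2157 without CT28 and CT32, 1500 without CT28, 913 without CT48, 19 with time points as the unit, 364 with an estimated correlation, 8561 as a straight line in CT28 to CT48 and 8126 without 24 h terms, and with replicates left out 1839 to 3888.

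CT24 against CT0 (1443) was 3991 with part weights, 4068 with only its 2 groups in the fit and 3832 with CT0 to CT24 only in the fit. With replicates left out it was 773 to 1487. The share higher was 60.4%, with 51.4% under quantile scaling and 64.3% without CT24 replicate 2. The rhythm difference (6778) was 4465 without CT28 and CT32, and 4940 to 6799 with replicates left out. CT48 against CT24 (2830 to 4056 with replicates left out), CT48 against CT0 (5031 to 5959) and any difference (8720 to 10844) stayed within 1.5 times under every setting run. Of the named genes' values under other settings, none for the contrasts or the trend with a step passed with the opposite sign. The naming rule made this likely in advance, as it required the same sign in both parts or groups without overlap. The rhythm value is an amplitude and has no sign, and peak times were not compared across settings. For the rhythm 903 kept their side of the threshold, 179 lost it and 76 gained it, and for the trend with a step 616 kept it and 84 lost it.

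The labels do not say that a replicate number marks a shared litter, batch or day. Same-numbered libraries had a mean correlation of 0.0242 (lowest -0.302), others -0.0081, and 29 of 51 correlated best with their own number, a hint of shared structure from the data and not from the design. With the replicate block the counts were 1725 (rhythm), 0 (trend), 3763 (trend with a step), 10865 (any), 1560 (CT24 against CT0), 4029 (CT48 against CT24), 6015 (CT48 against CT0) and 6845 (rhythm difference). Depth is unknown, so whether it limits the changes of low genes could not be tested. Genes at 0 numbered 78 to 238 per library in CT0 to CT24 and 196 to 446 in CT28 to CT48. A difference in depth between the parts is therefore possible, and low genes are uncertain across them.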

Other observations

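The interferon list, its test and its fits without single libraries were chosen after the genes with the largest changes had been seen.

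Several large changes were in interferon-induced genes, and a list of 25 others was drawn up that leaves out those already named. From CT0 to CT24, 14 of 25 rose and 0 fell (limma; 21 rose adjusted over the list alone), with a median log2 difference of 0.65. The viral RNA sensor Ifih1 rose by 0.66 ± 0.13 (SE, adjusted p = 0.00043), the transcription factor Irf7 by 1.08 ± 0.27 (adjusted p = 0.00769) and the guanylate-binding protein Gbp3 by 1.07 ± 0.27 (adjusted p = 0.00766). From CT24 to CT48, across the parts, 24 of 25 fell. Mean list scores were -0.764 at CT0, 0.73 at CT24, 1.42 at CT32 and -1.31 at CT48, and libraries of 1 time point differed widely, from -1.69 to 0.188 at CT0 and from -0.0875 to 1.3 at CT24 (n = 4 each).

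A hypothesis is that interferon-stimulated genes move as a group with time. The share that rose was 56%, and it was 23 of 25 with only CT0 to CT24 in the fit. On straight lines 24 of 25 rose from CT0 to CT24 and 15 of 25 fell from CT28 to CT48, with 0 in the other direction. The count from CT0 to CT24 depended on single libraries: 4, 6 and 7 members rose without CT0 replicate 3, CT0 replicate 2 and CT24 replicate 3, 9 without CT24 replicate 1, and 20 and 21 without CT0 replicate 4 and CT24 replicate 4. In camera p was 2.03e-14 at the preset correlation and p = 0.045 with an estimated correlation. A change with age and a difference between litters, which could each move these genes together, cannot be told apart, as litters are not given.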
